A study of Mus musculus with 2 samples.

How the data were processed

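RNA from mouse embryos of the B6CBF1 cross was measured by RNA sequencing in 2 libraries, 1 labelled Fresh and 1 labelled Cryo. Per the labels' protocols, 1 µL of sample went into each library with the Ovation SoLo kit, which is made for very small inputs. The number of embryos behind each library was not given in the sources used here. The group of each library was taken from its treatment label, which says whether transfer was done with or without vitrification and warming. The deposited tables' own names give the opposite condition: the table attached to the library labelled Fresh carries a name for cryopreservation, and the other a name for fresh embryos. Nothing in the sources used here settles which is right, so each library is called by its label, and exchanging them would turn every direction around.

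The authors deposited 1 table per library with 46202 gene records. Per the file headers, each record holds counts of reads over the gene, its exons, its exon-exon junctions and its introns, each as unique and as total reads. The same tables hold the authors' deposited FPKM values. Tested on the tables, FPKM equalled total exon reads divided by exon length and by 1 constant per library, which was 10229875 for the library labelled Fresh and 18237066 for the library labelled Cryo. For records without an annotated transcript, total gene reads and gene length took their place. These constants are read here as the number of mapped reads. Reads outside gene records were not counted directly. They were taken as that number less the total gene reads summed over all records. Other deposited columns give numbers of exons and transcripts and lengths in bases, per the file headers. The genome build was GRCm38 (mm10), per the submitters' processing notes. The aligner, the counting tool, strand handling and read filters are not given in the sources used here. MicroRNA data, which the title of the series mentions, were not analysed here.

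The count used for each gene was the read number behind its FPKM. Counts summed to 5817004 in the library labelled Fresh and 12038298 in the library labelled Cryo. Counts were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, and log2 ratios were formed as Cryo minus Fresh from CPM with a prior of 0.5 count. A gene was measured if it had at least 10 counts in 1 library. With 1 library per group there is no replicate check, and no p-value across genes was computed. A gene was instead counted as higher or lower by a fixed rule of size: a log2 ratio of at least 1 in either direction, at least 50 counts in the higher library, and a 95% counting interval that excluded equality. Intervals are exact conditional binomial (Clopper-Pearson) intervals. They cover counting error only, since reads copied by PCR are not independent molecules, and they compare these libraries, not the conditions. A gene at 0 in 1 library was given as a fold against a floor of 3 counts in that library.

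For 37 gene lists, the median log2 ratio of the measured members was placed among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries and is not a p-value. Of 988 symbols on the lists, 1 was not matched to a gene record. Synonyms were taken from a RefSeq gene table of the same assembly, in which 43040 of the gene identifiers were found. Named genes followed a rule: the 12 highest and 12 lowest log2 ratios among genes past the rule of size with at least 100 counts in the higher library, leaving out unnamed gene models and ribosomal protein pseudogenes. Added to these were up to 3 members of each list past the rule of size, or its most abundant members to make 2, with Actb, Gapdh and all sex-linked list members. The tables give no gene type, so mitochondrial tRNA genes stayed in. Some measured genes are not reported here by name. The lists, the rule of size and the rule for named genes were chosen before the data were examined.

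The rule of size was tested on simulated counts drawn from the means and totals of these libraries, with 200 genes changed. The changed genes were drawn from those with at least 200 counts over both libraries together. With counting error alone, 100% of genes changed by 1.5 on the log2 scale passed in the right direction, and 0.0331% of 15123 unchanged genes passed. With added noise of 0.35 on the log2 scale per library, 88% of such genes passed, and so did 3.83% of 15172 unchanged genes. The counting interval then covered 0 for 59.1% of the unchanged genes. In the data, genes with a mean of 50 to 200 reads had a standard deviation of the log2 ratio of 0.92. That is more than this noise gives, so these rates do not hold for genes near the limit of 50 counts. Alternatives set beforehand were other scalings (total counts, DESeq2 1.42.0 size factors, upper quartile, and totals without mitochondrial and the 100 most abundant genes), other count limits, a larger threshold, a larger prior, the deposited FPKM values, thinning the deeper library and exchanging the labels. Alternatives chosen after seeing the data used exon-exon reads, unique exon reads, reads over the whole gene body, or only records with an annotated transcript. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.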

Results

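The design compared embryos transferred after vitrification and warming with embryos transferred without it, which asks what vitrification leaves in the embryo's RNA. Vitrification is rapid cooling to a glass-like state with cryoprotectants. Embryos had been cultured for 3 days, and 6 blastocysts of each kind were transferred to the opposite uterine horns of pseudopregnant recipients 2.5 days after mating. The recipients were killed 4 days later. The labels call the sampled material embryo and do not say at which of these steps RNA was taken. The numbers of measured lineage genes, given below, bear on this. There was 1 library per group, so no value below has a replicate error. The deposited tables' names give the opposite condition to the labels, and "higher" and "lower" below refer to the library labelled Cryo relative to the library labelled Fresh.

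The libraries differed in depth. The library labelled Fresh held 5817004 counted reads and the library labelled Cryo held 12038298, a ratio of 2.07. Genes of the mitochondrial chromosome took 21.1% of counted reads in the library labelled Fresh (95% exact binomial interval 21.0 to 21.1) and 18.5% in the library labelled Cryo (18.5 to 18.5). Cytosolic ribosomal protein genes took 4.37% and 4.20%, and the 100 most abundant genes 43.4% and 42.9%. Introns held 36.4% of reads over genes with annotated transcripts in the library labelled Fresh and 31.2% in the library labelled Cryo. Reads outside gene records were 22.4% and 14.3% of mapped reads. At least 1 read was counted for 23102 genes in the library labelled Fresh and for 20658 in the deeper library labelled Cryo.

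Of 15490 measured genes, 814 were higher and 502 lower in the library labelled Cryo by the rule of size, and 91.5% were neither. Among 11845 protein-coding genes, 684 were higher and 303 lower. Higher genes made up 61.9% of those past the rule. With the library labelled Cryo thinned to the same total of counted reads as the other, 458 genes were higher and 507 lower, so that higher genes made up 47.5%. With all reads over the gene body they made up 42.2%, and with exon-exon reads 73.2%. Across 6055 genes with at least 100 reads in both libraries, Pearson's r of log2 CPM was 0.95; genes are not independent replicates. The standard deviation of the log2 ratio was 0.92 for genes with a mean of 50 to 200 reads, against a median counting error of 0.22. For genes with a mean of at least 1000 reads it was 0.36, against 0.05. Of genes with a mean of 50 to 200 reads, 20.3% had a log2 ratio of at least 1 in size. With a mean of at least 1000 reads, 1.11% did. A gene past the rule at few reads is thus often not unusual among genes of like expression.

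**Figure D1:**
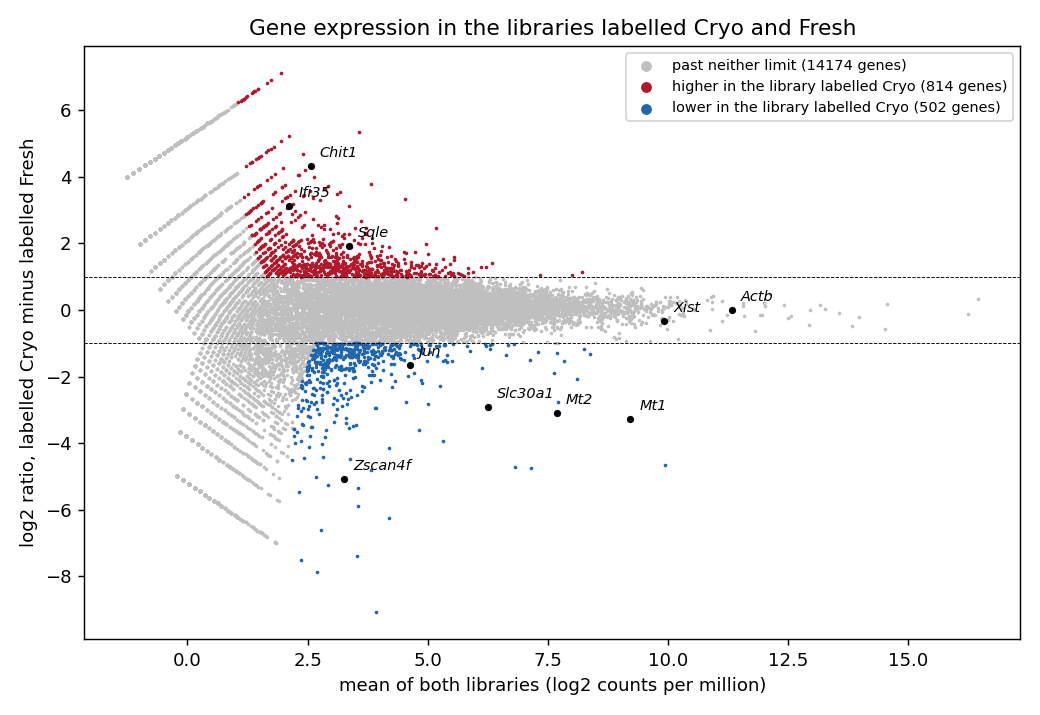
Each point is a measured gene, with its mean log2 CPM (counts scaled to library size) in both libraries on the x axis and its log2 ratio, labelled Cryo minus labelled Fresh, on the y axis; dashed lines mark log2 ratios of 1 and -1. The 814 red genes were higher and the 502 blue genes lower by the rule of size, and Mt1, Mt2 and Slc30a1 lie at log2 ratios of -3.29, -3.09 and -2.93.

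Mt1, Mt2 and Slc30a1 were lower in the library labelled Cryo. Mt1 and Mt2, the neighbouring genes of the metallothioneins that bind zinc and copper, had log2 ratios of -3.29 (95% counting interval -3.37 to -3.20) and -3.09 (-3.24 to -2.96). Mt1 (gene 17748, GRCm38 chromosome 8, 94179088 to 94180327) had 6284 reads in the library labelled Fresh and 1324 in the library labelled Cryo, and Mt2 had 2146 and 517. Slc30a1, which codes for a zinc exporter of the plasma membrane, had 784 and 211 reads and a log2 ratio of -2.93 (-3.16 to -2.71). With exon-exon reads, of which Slc30a1 had 28 and 20, its log2 ratio was -1.72, and its record overlaps another. The directions would be the opposite if the tables' names were right.

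Zscan4f, a gene known from early cleavage, had 109 and 6 reads and a log2 ratio of -5.08 (-6.70 to -4.06). It belongs to a family of near-identical copies, and with its 19 and 2 unique reads, under the limit of 50, the log2 ratio was -3.97. Rsc1a1 had 177 reads in the library labelled Fresh and 0 in the library labelled Cryo. That is 121-fold lower against a floor of 3 counts, with a counting interval that starts at 97.7-fold. Npm2 had 155 and 41 reads and Pigv 2116 and 641. Npm2 and Pigv were without an exon-exon read; Rsc1a1 has 1 exon, so it can have none, and 0 of its reads were unique. Rsc1a1 and Npm2 overlap another gene record, so the source of these reads is uncertain. B3glct had 120 and 50 reads and a log2 ratio of -2.29, but fell short of 1 in size with gene body reads. The mitochondrial tRNA genes TrnH, TrnK, TrnR and TrnW had log2 ratios of -2.84, -2.41, -2.31 and -2.21, from 328, 102, 185 and 284 reads in the library labelled Fresh.

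The 12 genes with the highest log2 ratios all had 11 or fewer reads in the library labelled Fresh. Chit1, which codes for a chitinase, had 3 and 136 reads and a log2 ratio of 4.32 (2.88 to 6.76). B3gnt2 had 1 and 102 reads with a log2 ratio of 5.23 (3.12 to 10.95), and Dnajc27 had 2 and 123 reads with one of 4.69 (3.02 to 7.96). Hpcal4, with 11 and 318 reads, had a log2 ratio of 3.77, but 1.44 with its 2 and 13 unique reads, which are under the limit of 50. Ddx11, a DNA helicase gene, had 3.72. The zinc finger genes Zfp937, Zfp324, Zfp791 and Zfp941 had 4.07, 3.98, 3.54 and 3.49. Ccnj, a cyclin gene, had 3.58, Tdpoz2 had 3.57, and Arntl2, a circadian transcription factor gene, had 3.45. With gene body reads Arntl2 and Zfp791 fell short of a log2 ratio of 1. Exon-exon reads in the library labelled Cryo numbered 0 for B3gnt2 and Hpcal4, 3 for Dnajc27, 10 for Zfp937 and 15 for Zfp941. They numbered 21 for Ccnj, 27 for Zfp324, 83 for Ddx11, 88 for Zfp791 and Arntl2, and 118 for Chit1. Tdpoz2 has 1 exon and can have none. Where few reads cross a junction, the source of the reads is uncertain.

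Of the 37 gene lists, 9 had medians outside the central 95% of matched random lists. Lists of genes drawn independently would give 1.85. Members of a real list can move together, so 1.85 is not a chance level for these lists. Lipid and cholesterol synthesis was higher in the library labelled Cryo, with a median log2 ratio of 0.37 over 26 measured genes at percentile 99.8. Of these, 4 were higher, none was lower, and 22 passed neither limit. Sqle, coding for squalene epoxidase, had 25 and 196 reads and a log2 ratio of 1.92 (1.33 to 2.59). Idi1, an isomerase of the isoprenoid pathway, had 1.27 (0.99 to 1.57), and 2.09 with its 15 and 141 unique reads. Cyp51, named after its value was seen, was also higher at 1.04. With exon-exon reads the list median was 0.25 at percentile 94.9, inside the central range. The names of the tables would make these genes lower with vitrification.

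Replication-dependent histone genes had a median of 0.24 over 35 genes at percentile 99.6, with 4 higher and 2 lower. Hist3h2a had a log2 ratio of 1.42 (1.23 to 1.62), Hist1h3b -1.57 (-1.81 to -1.34) and Hist2h4 -1.32. The other higher members, named after their values were seen, were Hist1h2be at 1.2, Hist2h2aa1 at 1.06 and Hist1h2ae at 1.02. These genes are near-identical copies whose reads can be divided between records. Of the 369 and 255 reads of Hist1h3b, 196 and 222 were unique, and with these its log2 ratio was -0.94. All reads of Hist3h2a and Hist2h4 were unique, so shared reads do not account for their ratios. With gene body reads Hist1h3b and Hist2h4 turned to 0.998 and 0.61, and the cause was not tested. Implantation and trophoblast invasion had a median of 0.33 over 17 genes at percentile 97.9, with 1 higher member, Hbegf, at 2.32 from 5 and 54 reads. Bsg, its most abundant member, had 0.33. Of the 200 genes nearest to Hbegf in mean expression, 28.5% differed as much. The implantation list lay above the central range in 4 of 9 alternatives. It lay inside at percentile 69.3 with the minimum of 100 counts, which kept 9 genes, 70.6 with exon-exon reads, 71.8 with gene body reads, 93.6 with unique exon reads and 92.6 with FPKM. The sex-linked list had a median of 0.66 over 5 genes at percentile 99.0, and lay inside the central range at 97.2 with gene body reads. The Y-linked genes Eif2s3y, Uty, Ddx3y and Kdm5d had log2 ratios of 1.17 (0.89 to 1.47), 0.94 (0.54 to 1.36), 0.66 and 0.04, and Xist, the RNA of the inactive X chromosome, had -0.34 (-0.39 to -0.30). Over the alternatives Uty ran from 0.48 to 1.90.

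The 5 lists with lower medians differed by small amounts. Preimplantation trophectoderm had a median of -0.19 over 18 genes at percentile 0.80, with none past the rule of size; Krt18, a keratin of that layer, had -0.19 and the glucose transporter gene Slc2a3 had 0.11. With exon-exon reads its percentile was 6.08, inside the central range, and with gene body reads 2.5, at its edge. Aquaporins and ion transport had -0.28 over 15 genes at percentile 1.99, with none past the rule and Aqp3 at -0.22. It lay inside the central range with exon-exon reads (percentile 24.8), gene body reads (12.6) and the minimum of 100 counts (10.4). Mitochondrially encoded genes had -0.17 over 15 genes at percentile 1.02, with Rnr2 at -0.12 and COX1 at 0.18; with gene body reads the percentile was 4.89, inside the central range. Nuclear-encoded respiratory chain genes had -0.10 over 51 genes at percentile 0.48, with 2 lower, Ndufa5 at -1.37 and Atp5k at -1.33. With gene body reads the percentile was 7.2, inside the central range, and both members fell short of a log2 ratio of 1 in size. Cytosolic ribosomal proteins had -0.10 over 73 genes at a percentile of 0, with none past the rule, Rpl4 at 0.04 and Rpl7 at 0.27; with unique exon reads the median was 0.02 at percentile 62.3. On the deposited FPKM scale, which moved the median gene by 0.19, the medians of the trophectoderm, mitochondrially encoded, respiratory chain and ribosomal lists were above 0. The names of the tables would turn these directions around.

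**Figure D2:**
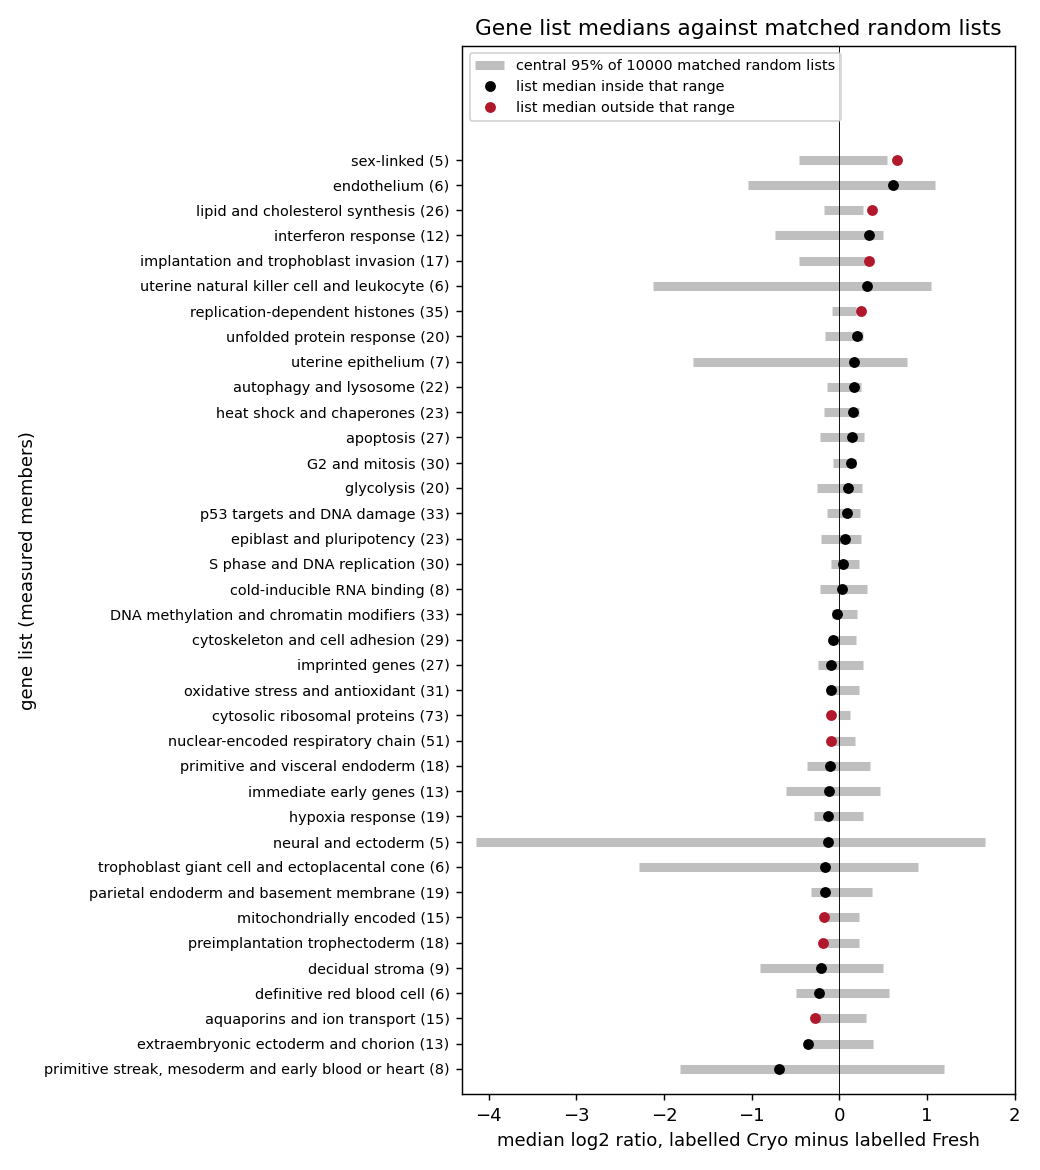
Each row is a gene list with its number of measured members, and each point is the median log2 ratio, labelled Cryo minus labelled Fresh, on the x axis; grey bars span the central 95% of 10000 random lists matched on size and expression. The 9 red medians lie outside their bars, with lipid and cholesterol synthesis at 0.37 and aquaporins and ion transport at -0.28.

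Lists of embryonic lineages mostly lay within the range of random lists. Epiblast and pluripotency had a median of 0.07 over 23 genes at percentile 63.4, with Gdf3 higher at 1.35 (0.92 to 1.83), and Fgf4 and Otx2 lower at -2.35 (-3.13 to -1.68) and -1.38. With gene body reads Otx2 fell short of a log2 ratio of 1 in size. Extraembryonic ectoderm and chorion had -0.36 over 13 genes at percentile 3.98, with Ddah1 at -0.36 and Fgfr2 at 0.10. Primitive and visceral endoderm had -0.11 over 18 genes, with Sox17, a transcription factor gene of endoderm, higher at 1.26 from 15 and 75 reads, and the abundant receptor gene Lrp2 at 0.23. Parietal endoderm and basement membrane had -0.16 over 19 genes, with Snai1 higher at 2.52 from 5 and 62 reads and Lamb1 at 0.15. Imprinted genes had -0.09 over 27 genes, with Cd81 and Plagl1 higher at 1.60 and 1.37. Among the 200 genes nearest in mean expression, 31.5% differed as much as Sox17, 30.5% as Plagl1, 17.5% as Snai1 and 11.5% as Cd81. For Gdf3, Fgf4 and Otx2 the share was 6.5%, 5.5% and 15.5%.

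Few genes of later or maternal cell types were measured. By contrast, preimplantation trophectoderm had 18 of 18 genes measured and epiblast and pluripotency 23 of 28. The low numbers for the later lists argue against embryos recovered 4 days after transfer. No embryos of known stage were compared, so the step is not settled. Of 31 giant cell and ectoplacental cone genes, 6 were measured, with a median of -0.16; Cited2 had 0.22. Primitive streak, mesoderm and early blood or heart had 8 of 30, with a median of -0.69, Runx1 at -0.61 and Wnt3a at -0.78. Neural and ectoderm had 5 of 17 with a median of -0.13, Nes at 0.33 and Otx1 at -1.0. Decidual stroma had 9 of 28 with a median of -0.21, Gja1 at 0.24 and Alpl at 0.15. Uterine epithelium had 7 of 23 with a median of 0.17, Wfdc2 higher at 1.31 and Epcam at 0.17. Uterine natural killer cell and leukocyte had 6 of 32 with a median of 0.32, H2-Ab1 higher at 2.25 from 7 and 71 reads and Cd74 at 0.11. Endothelium had 6 of 18 with a median of 0.61, Pecam1 at 0.38 and Tie1 at -0.63. Definitive red blood cell had 6 of 17 with a median of -0.23, Hbb-bs lower at -1.61 from 97 and 65 reads, of which 40 and 21 were unique, and Tfrc at 0.83. Among the 200 genes nearest in mean expression, 30.5% differed as much as Wfdc2, 23% as H2-Ab1 and 6% as Hbb-bs. None of the medians of these 8 lists of later or maternal cell types lay outside the central 95% of random lists. For such short lists that range was often wide. It ran from -4.14 to 1.66 for neural and ectoderm and from -2.29 to 0.89 for giant cell and ectoplacental cone. The narrowest, for definitive red blood cell, ran from -0.49 to 0.57. Lying inside is thus weak evidence for no difference.

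No stress list had a median outside the central 95% of random lists. Heat shock and chaperones had 0.15 over 23 genes, with Hspa4l and Hsf1 higher at 1.58 and 1.02 and Hspb8 lower at -1.05. Among the 200 genes nearest in mean expression, 21.5% differed as much as Hspa4l, 23% as Hsf1 and 19.5% as Hspb8. With unique exon reads Hsf1 had 0.94, short of the rule. With gene body reads Hspa4l, Hsf1 and Hspb8 all fell short of 1 in size, as did Hspa4l with exon-exon reads. Cold-inducible RNA binding had 0.03 over 8 genes, with Ybx1 at -0.26. Unfolded protein response had 0.20 over 20 genes, with Ddit3 lower at -1.15, short of 1 in size with gene body reads, and Hsp90b1 at 0.24. Oxidative stress and antioxidant had -0.10 over 31 genes, and its only members past the rule were Mt1 and Mt2, both lower. Apoptosis had 0.15 over 27 genes, with Endog, Cflar and Birc2 higher at 2.03, 1.68 and 1.22. With unique exon reads Cflar had 0.97, and with gene body reads Birc2 fell short of 1. The p53 and DNA damage list had 0.09 over 33 genes, with Xpc and Gadd45g higher at 1.62 and 1.13 and Plk2 lower at -1.25. Of genes similar in mean expression, 2% differed as much as Xpc, 43% as Gadd45g and 15.5% as Plk2. Interferon response had 0.34 over 12 genes, with Ifi35 higher at 3.11 from 5 and 94 reads and H2-K1 at 0.79. Autophagy and lysosome had 0.16 over 22 genes, with Atg5 higher at 1.69 (1.37 to 2.03) and Gabarapl2 at 0.41. Immediate early genes had -0.12 over 13 genes, with the transcription factor genes Jun and Jund lower at -1.65 (-1.97 to -1.35) and -1.54 (-1.82 to -1.28).

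Metabolic, chromatin, cycle and structural lists also lay within the range of random lists. Glycolysis had a median of 0.10 over 20 genes, with Pfkfb3, a regulator of glycolytic flux, lower at -3.03 from 54 and 13 reads. Hypoxia response had -0.13 over 19 genes, with Epas1 at -0.56 and Egln1 at -0.01. DNA methylation and chromatin modifiers had -0.03 over 33 genes, with Kmt2a lower at -1.01, short of 1 in size with gene body reads, and Tet2 at 0.03. S phase and DNA replication had 0.04 over 30 genes, with Gins2 lower at -2.13 from 50 and 23 reads and Rrm2 at -0.20. G2 and mitosis had 0.13 over 30 genes, with Mki67 at -0.11 and Top2a at 0.50. Cytoskeleton and cell adhesion had -0.07 over 29 genes, with Actg1 at 0.27. Of the reference genes, Actb had -0.01 (-0.04 to 0.01), with values from -0.09 to 0.37 over the alternatives. Gapdh had -0.39 (-0.44 to -0.33), and turned to 1.38 with unique exon reads, as its reads are shared with copies.

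**Figure D3:**
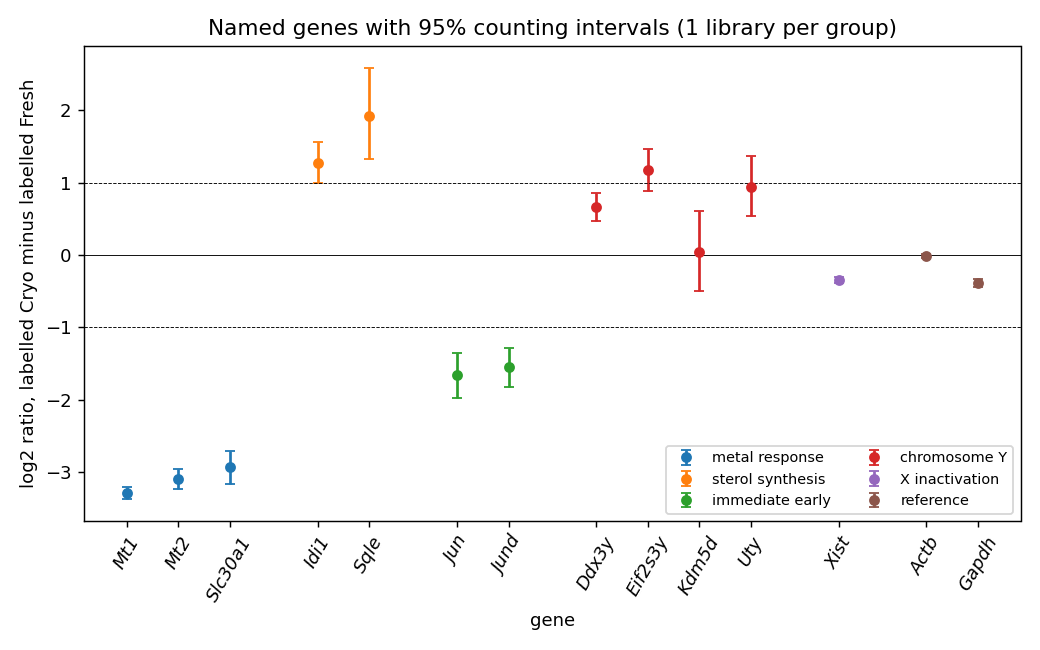
Points are log2 ratios, labelled Cryo minus labelled Fresh, of named genes along the x axis, bars are 95% counting intervals, and dashed lines mark 1 and -1. Mt1, Mt2 and Slc30a1 lie between -3.29 and -2.93, Idi1 and Sqle at 1.27 and 1.92, and Jun and Jund at -1.65 and -1.54.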

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

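Of the tests in this part, those of reads outside gene records and of the intron share of gene reads were chosen after the result was seen. The others were set before testing, but for a pattern already seen in these data. Reads outside gene records and in introns are data that the comparisons of counts do not use. Reads outside gene records were 22.4% of mapped reads in the library labelled Fresh and 14.3% in the library labelled Cryo. Within genes, the introns of 4 genes held many reads. Dgkb on chromosome 12 had 42404 intron reads in the library labelled Fresh and 21821 in the library labelled Cryo, with 0 exon reads in both. Cmss1 had 24437 and 45443, Cdk8 24168 and 33313, and Cd44 15371 and 28183. Exon reads were 16 and 129 for Cmss1, 365 and 871 for Cdk8, and 4 and 1 for Cd44.

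The library labelled Fresh had the higher share of intronic reads, by 5.28 points of gene reads. Relative to mapped reads the excess was smaller: unique intronic reads were 19.5% of mapped reads in the library labelled Fresh and 18.8% in the library labelled Cryo. Over 1753 silent receptor genes, the density of unique reads, relative to mapped reads, was 2.08 times as high as in the library labelled Cryo (1.90 to 2.27), so genomic DNA carried into that library is a candidate explanation for part of the pattern. That density, spread over introns, would give 120% of the excess relative to mapped reads, and 189% without Dgkb, which held 36.9% of it. It would give 16.9% of the difference in the share of gene reads and 15.2% of the excess outside gene records, which leaves the source of most of both open. More unspliced transcript of expressed genes also stays open. Relative to mapped reads, the excess of intron density in expressed genes was -0.70 times that in genes without an exon-exon read. By the bounds set beforehand, this value counted against more unspliced transcript, and genomic DNA met its own bounds. Neither verdict was kept, because the measure on gene reads, chosen after the result was seen, gave no clear answer. The scale of mapped reads falls with the reads outside gene records. Among gene reads of expressed genes, with the silent density taken out, the intron share was still 3.26 points higher in the library labelled Fresh. Beyond unspliced transcript, no biological explanation was tested.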

How the results depend on the processing

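Alternatives with exon-exon, unique exon or gene body reads, and with annotated records alone, were chosen after seeing the data. Under the 4 other scalings, 756 to 808 genes were higher and 505 to 558 lower. With no minimum in the higher library 1928 were higher and 2822 lower, with 200 counts 217 and 63, and with a log2 ratio of 2 205 and 135; these follow from the limits themselves. Thinning the library labelled Cryo left 458 higher, of which 417 were among the 814. The deposited FPKM values gave 198 and 86. Taking the groups from the tables' names gave 502 higher and 814 lower, by construction. Exon-exon reads gave 270 lower and gene body reads 1072; the cause was not tested.

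On the deposited FPKM scale, which raised the median gene by 0.19, list medians turned to 0.016 for preimplantation trophectoderm, 0.037 for mitochondrially encoded, 0.10 for nuclear respiratory chain and 0.11 for cytosolic ribosomal protein genes. Their percentiles stayed at 2.09 or lower. Medians there were 0.34 for heat shock, 0.36 for unfolded protein response, 0.10 for oxidative stress, 0.29 for glycolysis, 0.15 for chromatin modifiers, 0.23 for S phase, 0.32 for G2 and mitosis and 0.14 for cytoskeleton. With gene body reads, which raised the median gene by 0.12, medians were 0.045 for the respiratory chain and 0.024 for ribosomal proteins, both turned, and 0.25 for heat shock, 0.40 for unfolded protein response, 0.53 for lipid synthesis, 0.12 for chromatin modifiers and 0.76 for histones; Hist1h3b and Hist2h4 turned to 0.998 and 0.61. With exon-exon reads, medians were -0.65 for extraembryonic ectoderm, 0.29 for glycolysis, -0.23 for chromatin modifiers, 0.0066 for G2 and mitosis and -0.25 for ribosomal proteins. With unique exon reads they were -0.44 for extraembryonic ectoderm, 0.055 for G2 and mitosis and 0.022 for ribosomal proteins, which turned. Extraembryonic ectoderm had -0.40 with the upper quartile and -0.39 without mitochondrial and abundant genes. Beyond the shifts of scale, the cause was not tested.

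The other 288 list values stayed within the main median's range, an interval taken from the ranked log2 ratios of the list's members. For lists of 6 genes it runs from the lowest to the highest member, such as -5.81 to 5.60 for giant cell and ectoplacental cone. For lists of 5 genes it was widened to hold each value, so they could not leave it. Staying within the range is thus weak evidence for short lists. Of 1020 values of 105 named genes, 824 stayed within the counting interval, 194 left it without a called gene changing sign, and 2 reversed. Of 61 named genes past the rule, 14 fell short of a log2 ratio of 1 with gene body reads, or turned: Arntl2, Atp5k, B3glct, Birc2, Ddit3, Hist1h3b, Hist2h4, Hsf1, Hspa4l, Hspb8, Kmt2a, Ndufa5, Otx2 and Zfp791. So did 3 of 56 with unique exon reads (Cflar, Hist1h3b and Hsf1) and 2 of 43 with exon-exon reads; the cause was not tested. Alternatives for files with normalized values alone did not apply. No paired analysis was possible because each group has 1 library. Depth limits how closely genes with few reads are measured: the median counting error of the log2 ratio was 0.22 at a mean of 50 to 200 reads and 0.05 at 1000 or more. By construction, genes under 50 counts in both libraries were never counted as higher or lower.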

Other observations

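Tests here on Mt1, Mt2 and Slc30a1 were chosen after the result was seen, except that of Slc39a10. The tests on numbers of genes were set before, apart from the counts on annotated records and on other kinds of reads. Those set before, that of Slc39a10 included, were set before testing but for patterns already seen in these data. All 18 measured mitochondrial tRNA genes had log2 ratios below 0, with a median of -1.89, and 10 were lower and 0 higher by the rule of size. The 13 mitochondrial mRNAs had a median of -0.17. Among 19 measured zinc transporter genes, 3 passed the rule: Slc30a1, Slc30a2 at -2.97 from 90 and 23 reads, and Slc30a9 at 1.45 from 56 and 315 reads. Slc30a2 and Slc30a9 were named after their values were seen.

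Mt1, Mt2 and Slc30a1, known targets of the zinc-sensing transcription factor MTF-1, were lower together in the library labelled Cryo. The median of the 3 genes was at most -3.10 over 4 scalings and thinning. The scalings moved the median gene by only -0.046 to -0.008 and thinning by 0.0005. Shifts of that size are far too small to account for these ratios, so the outcome was all but fixed in advance. With unique exon reads, which leave out reads shared with copies, the median of the 3 genes was -3.17. Of 2063 other genes at least as abundant, 3 unnamed gene models differed as much, 0.145%, against few-molecule sampling, though the 3 genes were picked for their size. A difference in available zinc may account for the pattern. Slc39a10, which MTF-1 represses under zinc, was higher by 0.57 (0.36 to 0.80), under the 0.58 set beforehand. For genes with a mean of 200 to 1000 reads, the standard deviation of the log2 ratio was 0.47. A value of 0.57 is thus not unusual for such a gene, and the zinc explanation stays open. Handling, culture medium, vitrification and chance differences between embryos cannot be told apart with 1 library per group, and which library was vitrified is itself unsettled, as no list here marks vitrified embryos.

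More genes were higher than lower in the library labelled Cryo, 61.9% of those past the rule. After thinning to the same total of counted reads the share was 47.5%, consistent with unequal totals as one source of the imbalance. Thinning lowered the share for other kinds of reads too, from 73.2% to 57.7% with exon-exon reads, 64.7% to 50.2% with unique exon reads and 42.2% to 31.1% with gene body reads. With gene body reads lower genes outnumbered higher ones although the totals were unequal there too, so the kind of reads also sets the balance. The libraries still differed in other ways: at least 1 read was then counted for 18870 genes against 23102 in the library labelled Fresh, and at least 10 for 11971 against 13289. Fewer distinct molecules in the library labelled Fresh would leave more genes nearly missing from it. After thinning, such genes were 0.367 times as many as those nearly missing from the library labelled Cryo (11 and 30, interval of the ratio 0.17 to 0.75). By the bounds set beforehand that counted against it. Among records with an annotated transcript they were 9 and 10, a ratio of 0.9 (0.32 to 2.46), so the difference rests mostly on other records. Those are counted over their whole length, where the higher density over silent genes in the library labelled Fresh could add reads. The test thus cannot decide whether that library held fewer molecules. No biological explanation was tested.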
